A study of Mus musculus with 18 samples.

How the data were processed

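Reduced representation bisulfite sequencing was used on genomic DNA from 18 mouse samples in 7 groups, taken from the sample labels, which also number the samples of each group. The labels do not say whether the samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The deposited tables hold, for each CpG and strand, a count of methylated reads and a count of all reads, and a score that the authors set from their ratio. The counts were used as deposited and the score was not used. Coordinates are on build mm9, per the submitters' processing notes, and are printed here counted from 1. The aligner, the methylation caller and any filters are not given in the sources used here. CpGs that the aligner cannot place, and single base differences between the strains used and the reference genome, would enter such counts as missing or altered values and were not examined.

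Counts of both strands of a CpG were added. A CpG was used in a sample at 5 or more reads. The level of a sample was the mean over CpGs that reached 5 reads in all 18 samples, weighting each CpG equally. For the tile test, methylated and total reads were summed over CpGs in fixed windows of 1 kb that held at least 3 such CpGs in every sample. Tiles with 30 or more CpGs are called dense. A quasi-binomial logistic model with 7 group means was fitted to every tile in all samples, with the dispersion moderated across tiles by an empirical Bayes step that gave the same values as limma's squeezeVar, and set to at least 1. F tests were adjusted by the Benjamini-Hochberg method in each comparison. A tile is called, and written as higher or lower, at an adjusted p under 0.05 and a difference between group means of at least 20 points. Values with 1 number per sample were compared by 2-sided exact permutation tests, adjusted within each family of comparisons. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.

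The model was tested on simulated counts for the 33545 tiles, with 100 tiles lowered by 25 points and 100 by 40 in the first group. All other tiles had the same mean in every sample, with a spread set by the fitted dispersion. The lowered tiles were drawn only from those of intermediate to high level over all samples, and no tile was raised. Recovery of higher calls, and of changes at tiles of low level, was thus not measured. No difference between library types (defined below) was simulated, so false calls in the data may be more frequent than here. For female ESC against female MEF, 80% and 100% were recovered with 2 false calls. For SSEA1+ against MEF these were 54% and 95% with 4, for SSEA1+ against SSEA1− 45% and 90% with 10, and for female against male MEF 75% and 96% with 10. In that last comparison 10.6% of unchanged tiles had an unadjusted p under 0.05, against 5.15 to 6.01% in the others; the cause was not tested.

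Tiles named in the text followed a rule fixed before the data were examined: for each comparison, the 3 largest differences in each direction among called tiles whose samples do not overlap, 1 per 100 kb, and the same on the X. A few of them are given in the text. The gene table in hand is on another build, so no gene or promoter was assigned, and the 11 gene lists fixed beforehand and the promoter tests were not analysed here. Chromosome Y was not analysed here. The position between MEF and ESC used separate samples for choosing tiles and for measuring. Reads per chromosome were compared as log2 ratios of tile totals to female MEF of the same library type, for tiles with at least 100 reads, with a pseudocount of 0.5 reads and centred on the autosomal median. The overlap of SSEA1 and iPSC tiles was tested in strata of 10 points of the SSEA1 level, 10 points of the female MEF level and 4 classes of reads, by the exact sum of hypergeometric distributions. A matched value compares tiles only with those of other autosomes at like CpG number, level and change of level.

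The alternatives fixed beforehand were a minimum of 10 or 3 reads, limma on log2 ratios of methylated to unmethylated reads with a prior count of 1, a replicate block, reads per CpG capped at 50, dense tiles of 20 CpGs, each sample's own CpGs, a read-weighted level, exchanged samples for the position, and leaving out each sample in turn. Alternatives chosen after seeing the data were tiles of only those CpGs that reached 5 reads in all samples, library type as a term, values within library types (also at 10 reads, over tiles of 20 CpGs, over own CpGs and read-weighted), a background correction, leaving out chromosome 11, and the X tiles low in male samples with their own alternatives. Library type was set from the percentage of CpGs read on both strands, under 8% for type C and over 14% for type B. The correlation of log2 reads per tile between type C and other libraries was at most 0.495, and within type C at least 0.806. Types A and B were not separated by this measure: the highest correlation between types was 0.824 and the lowest within a type 0.713. Reads without molecular identifiers are not independent molecules, so counting error is a lower limit on the error; the moderated dispersion had a median of 2.13 times binomial.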

Results

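DNA methylation was measured by reduced representation bisulfite sequencing, which digests genomic DNA with a restriction enzyme, keeps short and CpG-rich fragments, and reads methylated cytosines as protected from conversion. The 18 mouse samples covered 7 groups. These were female embryonic stem cells (ESC, n = 4), male ESC (n = 2), female induced pluripotent stem cells (iPSC, n = 2), female mouse embryonic fibroblasts (MEF, n = 4), male MEF (n = 2), and a pair of female populations taken during reprogramming. Those populations were separated by the surface antigen SSEA1, which is carried by mouse pluripotent cells: SSEA1+ (n = 2) and SSEA1− (n = 2). The series title names X chromosome reactivation during reprogramming as its subject, so the comparisons asked where methylation differed between sexes, between the start and end cell types, and in the intermediates, on autosomes and on the X.

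Total reads over CpGs were 11424460 to 18987617 per sample in female ESC, 12365786 and 23712140 in male ESC, 31492063 and 34513354 in iPSC, 11833113 and 23566525 in SSEA1+, 23408025 and 34479499 in SSEA1−, 15691149 to 46130295 in female MEF, and 16125958 and 62920167 in male MEF. In all 18 samples, 148842 autosomal and 7124 X CpGs held at least 5 reads. The tile test used 33545 tiles of 1 kb, 1350 of them on the X, with a median of 189 reads per tile and sample. Libraries fell into 3 technical types by the percentage of CpGs read on both strands, which the labels do not record. Type A (9.03 to 11.7%) held all ESC, 1 female and 1 male MEF library. Type B (15.2 to 16.05%) held all 4 SSEA1+ and SSEA1− libraries, 1 female and 1 male MEF library. Type C (7.25 to 7.46%) held both iPSC and 2 female MEF libraries, MEF 3 and 4. The tile levels of female MEF 3 and 4 had a Pearson correlation of 0.996, against 0.974 to 0.986 for the other pairs of female MEF. They may not be independent samples, so n = 4 may overstate the replication of female MEF. Differences within a type, where both groups have one, are given beside most pooled values. Type and group could not be separated directly for iPSC against ESC or against SSEA1+, which share no type.

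**Figure D1:**
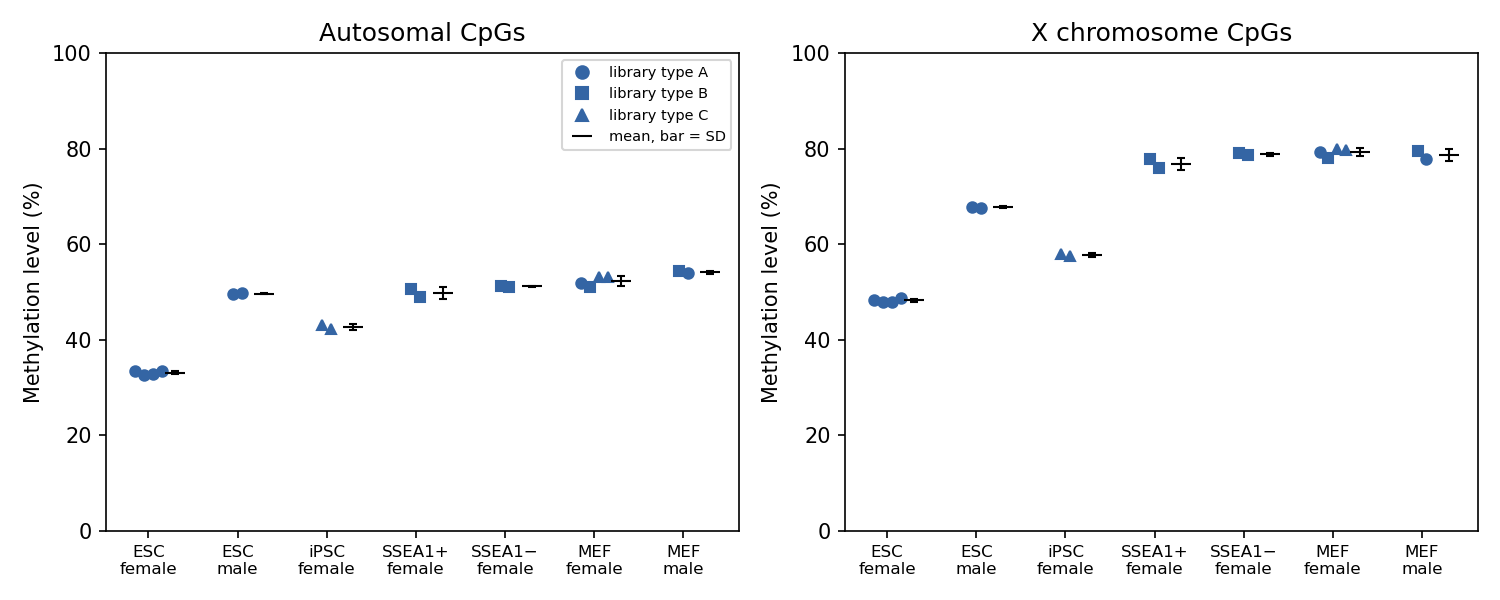
Mean methylation level (%, vertical axes) of autosomal CpGs (left) and X chromosome CpGs (right) in each of the 18 samples; symbols give the library type and the black marks the group mean with its SD. Female ESC were lowest on both, at 33.0% and 48.2%, and female MEF stood at 52.2% and 79.2%.

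Over the CpGs read in all samples, female ESC were far less methylated than male ESC, but few dense tiles were called lower. The mean autosomal level was 33.0% ± 0.333 (SD, n = 4) in female ESC and 49.6% ± 0.118 (SD, n = 2) in male ESC, a difference of -16.5 points. On the X, the level was 48.2% ± 0.343 in female and 67.7% ± 0.192 in male ESC. Of the tiles tested, 8992 were lower and 12 higher in female ESC. The lower tiles were 33 of 6577 dense tiles (0.50%) and 33.2% of the other tiles. Dense autosomal tiles stood at 4.05% in female and 5.20% in male ESC, which leaves little room for a lower call. Dense X tiles stood at 12.8% and 16.3%, and 1 of 148 was lower. A tile on chromosome 7 (134755001 to 134756000, 8 CpGs) stood at 7.96% ± 2.59 in female and 96.1% ± 0.0374 in male ESC, and in iPSC at 59.7% ± 7.72. On chromosome 5 (150411001 to 150412000), the levels were 9.55% ± 4.45 and 95% ± 7.07. On the X, 310 tiles were lower and 1 was higher in female ESC. The X tile with the largest difference (151740001 to 151741000) stood at 14.2% ± 4.73 in female and 84.5% ± 0.810 in male ESC. All 6 ESC libraries were of type A, so library type did not enter this comparison. The 2-sided exact permutation p of the autosomal difference was 0.0667, the smallest that 4 against 2 samples allow, and 0.122 after Benjamini-Hochberg adjustment over 11 comparisons.

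In MEF, the sexes differed at a larger share of tiles on the X, where female cells were higher, than on autosomes. Of 1350 X tiles, 226 (16.7%) were higher and 4 lower in female MEF, against 45 higher (0.140%) and 292 lower (0.907%) among autosomal tiles. The odds of a higher call were 144 times greater on the X (Fisher's exact test over tiles, p = 2.36e-273; tiles are not independent replicates). Dense X tiles (30 or more CpGs) carried 44.9% ± 1.23 (SD, n = 4) in female and 31.6% ± 0.404 (SD, n = 2) in male MEF. That difference of 13.2 points was 12.4 in type A and 12.1 in type B, with 1 library of each sex in each, 8.36 over tiles of at least 20 CpGs and 18.8 at a minimum of 10 reads. Autosomal dense tiles stood at 8.99% ± 0.964 and 8.65% ± 0.425. The X tiles with the largest differences were at intermediate levels in female MEF and near 0 in male MEF: 48.0% ± 7.79 against 2.94% ± 4.16 at 6356001 to 6357000, 42.2% ± 6.92 against 2.71% ± 3.83 at 98494001 to 98495000, and 42.8% ± 4.94 against 4.13% ± 1.42 at 130830001 to 130831000. The opposite direction was seen at X 11715001 to 11716000, with 32.0% ± 2.21 in female and 78.6% ± 11.6 in male MEF. On autosomes the mean level differed by -1.79 points (52.2% ± 0.962 and 54.0% ± 0.287; exact permutation p = 0.133; -1.95 within type A and -3.19 within type B). Over each sample's own CpGs the pooled difference was 2.70 points, but -3.02 within type A and -3.51 within type B. The dense X difference had an exact permutation p of 0.0667, the smallest that 4 against 2 samples allow. The split of calls depended on the test: 271 tiles were higher and 296 lower in all, 208 and 43 with limma, and 110 and 74 at 10 reads. The total of 567 tiles became 337 when the model was fitted without male MEF 1 and 918 without male MEF 2, and without male MEF 1 the call was lost in 6 of the 7 tiles named by rule. When all 8 female MEF, SSEA1+ and SSEA1− samples were set against male MEF, dense X tiles were higher by 11.04 points (exact permutation p = 0.0222, adjusted 0.0833 over 10 comparisons; 12.4 within type A and 9.71 within type B), 6.55 over tiles of at least 20 CpGs and 16.6 at 10 reads. Only the female side of this pool held SSEA1+ and SSEA1− samples, so sex was mixed with cell state. The labels do not say whether SSEA1+ and SSEA1− samples came from the same cultures.

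The sex difference was not alike in ESC and MEF. Subtracting the MEF difference from the ESC difference gave -14.7 points for the autosomal level and -16.8 points for dense X tiles. The dense X value had an exact permutation p of 0.00444 with sex labels permuted within each cell type over 225 relabellings, the smallest they can give, and 0.157 with cell type labels permuted within each sex over 420 relabellings. For the autosomal level the same tests gave exact permutation p = 0.0667 and 0.0381. Permuting sex labels assumes no sex difference in either cell type, and permuting cell type labels no cell type difference in either sex. Neither p thus tests the difference of the sex differences alone. In the tile model, 6041 tiles had a sex difference that differed between ESC and MEF, 5992 of them more negative in ESC, and 2873 without male MEF 1.

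Female ESC were much less methylated than female MEF, on autosomes and more often on the X. The autosomal level was 33.0% ± 0.333 in ESC and 52.2% ± 0.962 in MEF, a difference of -19.2 points (n = 4 and 4; exact permutation p = 0.0286, adjusted 0.122; -18.8 within type A, 4 libraries against 1). Of all tiles, 12597 were lower and 300 higher in ESC. On the X, 982 tiles (72.7%) were lower and 0 were higher, against 36.1% lower and 0.932% higher on autosomes; the X was more methylated in MEF, which leaves more room for a lower call. Dense X tiles fell from 44.9% ± 1.23 in MEF to 12.8% ± 0.255 in ESC (exact permutation p = 0.0286, adjusted 0.0833), and 123 of the 148 were lower. On chromosome 10 (44161001 to 44162000), ESC stood at 1.56% ± 3.12 and MEF at 94.5% ± 2.63. On chromosome 11 (87218001 to 87219000), the levels were 3.13% ± 2.28 and 94.8% ± 1.98. On the X (91168001 to 91169000, 16 CpGs), they were 14.2% ± 4.45 and 95.2% ± 0.438. Among the fewer tiles that were higher in ESC, chromosome 3 (143972001 to 143973000) stood at 69.0% ± 8.61 in ESC and 11.3% ± 4.84 in MEF, and chromosome 6 (117277001 to 117278000) at 67.1% ± 7.13 and 11.6% ± 8.80. Each of these named tiles kept its call without any 1 of the 8 libraries.

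Female iPSC were less methylated than female MEF, most of all on the X, and lay between female and male ESC in autosomal level. The level was 42.7% ± 0.633 (SD, n = 2), -9.60 points from female MEF and -10.4 within type C, 2 libraries against 2. The size depended on the measure: within type C the difference was -4.56 points at a minimum of 10 reads, -11.7 over each sample's own CpGs and -15.1 read-weighted, and pooled over types -3.58 at 10 reads and -5.77 over own CpGs. Of all tiles, 7728 were lower and 857 higher in iPSC than in MEF. On the X, 718 tiles (53.2%) were lower and 1 was higher, against 21.8% lower and 2.66% higher on autosomes. The X was more methylated in MEF, which leaves more room for a lower call. Dense X tiles stood at 15.7% ± 0.197, -29.1 points from female MEF and -30.1 within type C. A dense tile on chromosome 5 (93371001 to 93372000, 57 CpGs) stood at 4.89% ± 1.0 in iPSC, 3.79% ± 2.99 in female ESC and 92.5% ± 1.32 in MEF. On the X (98717001 to 98718000), iPSC stood at 4.12% ± 0.514, female ESC at 2.48% ± 2.03 and MEF at 78.2% ± 5.31. Some tiles were higher in iPSC: chromosome 3 (143972001 to 143973000) stood at 89.1% ± 5.02 in iPSC, and chromosome 7 (112926001 to 112927000) at 78.7% ± 8.79, against 0.887% ± 1.41 in MEF. The exact permutation p of the autosomal and dense X differences was 0.0667, the smallest that 2 against 4 samples allow.

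Compared with female ESC, iPSC carried more methylation on autosomes and on the X. The autosomal difference was 9.61 points (exact permutation p = 0.0667, the smallest possible; 16.4 over own CpGs), and 3769 tiles were higher and 83 lower. The X level was 57.7% ± 0.370 in iPSC and 48.2% ± 0.343 in female ESC, and 119 X tiles were higher (8.81%, against 11.3% on autosomes) and 4 lower. With library type as a term, a fit chosen after seeing the data that bridges both groups only through MEF, 1030 were higher and 99 lower. The tile on chromosome 5 (150411001 to 150412000) that separated female from male ESC stood at 79.6% ± 0.0394 in iPSC, and a dense tile on chromosome 13 (120277001 to 120278000, 42 CpGs) at 74.7% ± 1.99, against 4.79% ± 3.91 in female ESC. Both kept their calls with library type as a term. At tiles that were unmethylated in male cells, iPSC also read 3.77% and 3.94% as the median autosomal level, against at most 1.03% in every other library, which sets a floor under their low values. Corrected for this background, a step chosen after seeing the data, the autosomal difference from female ESC was 7.63 points, and that of dense X tiles 0.0431 points, against 2.996 as read. Against male ESC, iPSC differed by -6.93 points on autosomes (exact permutation p = 0.333, the smallest that 2 against 2 samples allow), by -4.61 at 10 reads and by -1.79 over own CpGs. Female ESC and iPSC together were lower than male ESC by a difference of -13.3 points (n = 6 and 2; exact permutation p = 0.0357, adjusted 0.122; -16.5 within type A, which holds no iPSC). Only the female side of this pool held iPSC, so sex was mixed with cell type.

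Over CpGs read in all samples, SSEA1− and SSEA1+ cells had autosomal levels close to those of MEF. The level was 51.1% ± 0.194 in SSEA1− and 49.8% ± 1.23 in SSEA1+, differing from female MEF by -1.14 (exact permutation p = 0.200) and -2.46 points (exact permutation p = 0.0667), and within type B, against 1 MEF library, by 0.0550 and -1.27 points. Read-weighted, the differences from MEF were -6.58 and -9.67 points (exact permutation p = 0.0667 for each), and -3.20 and -6.30 within type B. Over own CpGs they were -7.53 and -12.6 points, but 0.331 and -4.74 within type B, where SSEA1+ 2 stood at 34.7% and SSEA1+ 1 at 43.7%. Without SSEA1+ 2, the main difference of SSEA1+ was -1.59 points. Between SSEA1− and MEF, 571 tiles were lower and 104 higher. On chromosome 16 (92680001 to 92681000), SSEA1− stood at 3.43% ± 3.23 and MEF at 91.1% ± 4.90, on chromosome 2 (166105001 to 166106000) at 6.05% ± 8.55 and 90.2% ± 6.19, and on chromosome 5 (125561001 to 125562000) at 2.17% ± 0.50 and 79.9% ± 10.8. In SSEA1+ these 3 tiles stood at 47.4% ± 3.20, 41.1% ± 5.10 and 35.7% ± 15.1. Between SSEA1+ and MEF, 780 tiles were lower and 148 higher. On chromosome 11 (76171001 to 76172000), SSEA1+ stood at 9.52% ± 13.5 and MEF at 86.6% ± 5.26, with SSEA1− at 23.8% ± 0.297. On chromosome 19 (16158001 to 16159000), SSEA1+ stood at 16.2% ± 7.17, against 92.0% ± 2.96 in MEF, 92.0% ± 11.4 in SSEA1− and 89.8% ± 1.22 in iPSC. On the X, 9 tiles were lower and 2 higher in SSEA1−, and 7 lower and 0 higher in SSEA1+. The counts depended on single libraries: SSEA1− against MEF gave 1067 tiles without MEF 2, 393 without MEF 3 and 378 without MEF 4, and SSEA1+ against MEF gave 343 without SSEA1+ 1 (18 higher) and 593 without SSEA1+ 2 (152 higher), so most higher calls in SSEA1+ depended on SSEA1+ 1. With library type as a term the totals were 152 and 344.

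SSEA1+ and SSEA1− cells differed from each other at few tiles, and those higher in SSEA1+ overlapped with the tiles higher in iPSC than in MEF. Of 440 tiles, 267 were lower and 173 higher in SSEA1+. Of the 267 lower tiles, 134 (50.2%) were also lower in iPSC than in MEF, against 119 expected among tiles of like level and reads (exact stratified test, p = 0.0339). Of the 173 higher tiles, 65 (37.6%) were also higher in iPSC, against 32.6 expected in that way (exact stratified test, p = 6.01e-12). This test was chosen after seeing the data. No library was used in both comparisons, and neighbouring tiles are not independent. On chromosome 12 (77628001 to 77629000), SSEA1+ stood at 26.2% ± 8.77 and SSEA1− at 96.2% ± 0.652. Both groups were of type B. The autosomal level differed by -1.32 points (exact permutation p = 0.333, the smallest that 2 against 2 samples allow), by -0.773 at 10 reads, by -3.09 read-weighted and by -5.07 over own CpGs. It was -0.453 points without SSEA1+ 2 and -2.20 without SSEA1+ 1. Without SSEA1+ 2 the count was 355 with 188 higher and 167 lower, and without SSEA1+ 1 it was 213 with 37 higher and 176 lower. The higher tiles thus rest largely on SSEA1+ 1, and their overlap with iPSC was not tested without it.

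The iPSC were lower than SSEA1+ cells at more tiles than they were higher, and most clearly on the X, whereas the autosomal mean depended on the CpGs used. Of all tiles, 6744 were lower and 1238 higher in iPSC, and on the X 583 (43.2%) were lower and 1 was higher. The autosomal difference was -7.13 points and that of dense X tiles -23.8 points (39.6% ± 1.20 to 15.7% ± 0.197; exact permutation p = 0.333 for each). At 10 reads these were -1.23 and -15.5 points. The autosomal difference was -3.29 read-weighted and turned to 6.83 over own CpGs. The groups share no library type; with type as a term, 5983 tiles were lower and 407 higher. On chromosome 5 (114393001 to 114394000), SSEA1+ stood at 94.9% ± 5.42, iPSC at 6.76% ± 0.542 and female ESC at 3.38% ± 3.59. On the X (154006001 to 154007000), the levels were 84.2% ± 15.3, 7.34% ± 0.124 and 6.68% ± 2.35. Chromosome 18 (55012001 to 55013000) went the other way, from 12.4% ± 17.5 in SSEA1+ to 87.6% ± 7.0 in iPSC.

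Placed on a scale from female MEF (0%) to female ESC (100%), the intermediates lay near MEF and iPSC near ESC. The tiles were selected with samples 1 and 2 of each end group and the distances measured against samples 3 and 4. MEF 3 and 4, which set 0%, were of type C, as were the iPSC. All SSEA1+ and SSEA1− libraries were of type B and all ESC of type A. The female MEF library of type B had an autosomal level of 51.1%, against 53.1% and 53.0% in MEF 3 and 4. Small distances from MEF on this scale may therefore reflect library type, which was not tested. Over 11013 autosomal tiles that were lower in ESC, SSEA1− lay at 4.42% ± 0.454, SSEA1+ at 11.3% ± 4.01 and iPSC at 73.7% ± 2.23 (SD, n = 2 each). Over 956 X tiles, they lay at 5.13% ± 0.604, 9.57% ± 2.94 and 83.9% ± 0.00597. Over 331 autosomal tiles that were higher in ESC, SSEA1− lay at -20.4% ± 0.0360, SSEA1+ at 20.5% ± 12.3 and iPSC at 156% ± 6.53, beyond female ESC. Male ESC lay at 206% ± 7.54 there, at 44.8% ± 0.802 on autosomal tiles lower in ESC and at 66.6% ± 0.304 on X tiles. The scale thus depends on which ESC set its end. Sex could not be separated from the cell line of the ESC, which the labels do not give. With the roles of the samples exchanged, SSEA1− lay at 5.92% on those higher tiles, so its sign there was not stable, and SSEA1+ at 32.5%. Male MEF lay at 17.9% and, exchanged, at 34.0% there, as far as SSEA1+, and at 12.7% on X tiles, so these positions do not set SSEA1+ apart from MEF of the other sex. On autosomal tiles lower in ESC, male MEF lay at -4.03%. On X tiles, SSEA1− lay at 2.35% with the roles exchanged.

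**Figure D2:**
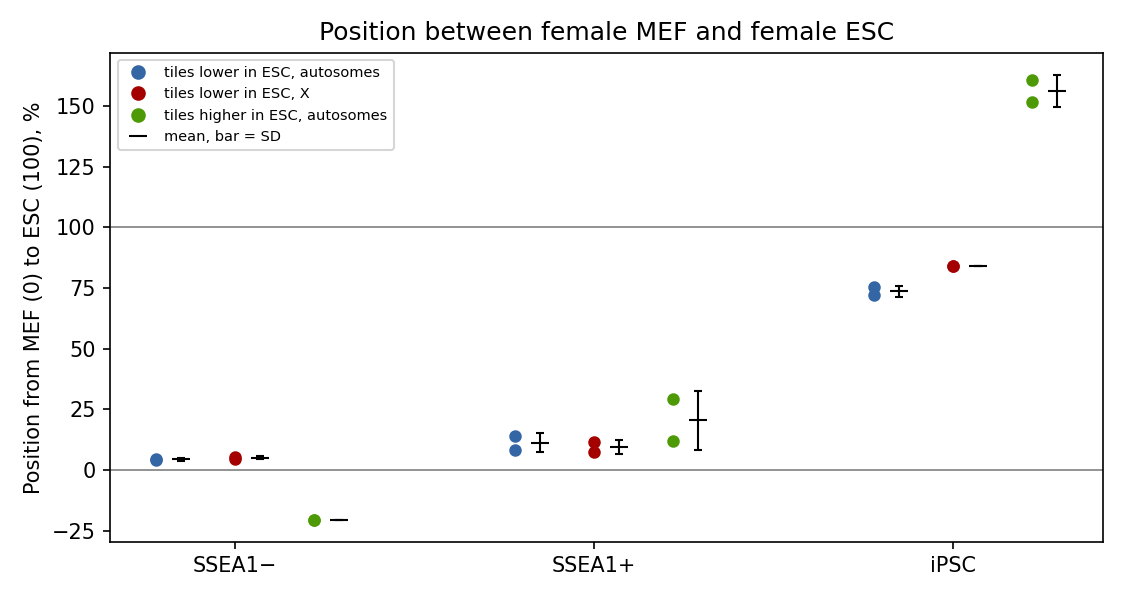
Position of each SSEA1−, SSEA1+ and iPSC sample on the scale from female MEF (0%) to female ESC (100%, vertical axis), for autosomal and X tiles lower in ESC and autosomal tiles higher in ESC; points are samples and black marks the mean with its SD. SSEA1+ averaged 11.3% and iPSC 73.7% on autosomal tiles lower in ESC.

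Methylation of X tiles that are unmethylated in cells with 1 X chromosome was present in MEF and both intermediates, and was at background in iPSC and ESC. This measure was chosen after seeing the data. It took the 254 X tiles under 10% in all 4 male samples, and as background the 12520 autosomal tiles chosen in the same way. The X tiles stood at 23.9% ± 1.89 in female MEF (n = 4), 20.6% ± 0.876 in SSEA1− (n = 2), 17.9% ± 1.32 in SSEA1+ (n = 2), 4.80% ± 0.101 in iPSC (n = 2) and 1.13% ± 0.0664 in female ESC (n = 4). The autosomal background was 1.47%, 0.635%, 0.731%, 4.84% and 1.02%. Group means exceeded 10% at 233 of the X tiles in MEF, 225 in SSEA1−, 216 in SSEA1+, 13 in iPSC (5.12%, against 6.19% of autosomal tiles) and 0 in female ESC. Read numbers on the X, given below, leave open a loss of an X in some iPSC cells, which could also lower this measure there. The 4 SSEA1+ and SSEA1− samples together were below the 4 MEF samples by a difference of -4.59 points (exact permutation p = 0.0286, adjusted 0.107 over 8 comparisons). Within type B, with 1 MEF library, the difference was -2.30 points, -3.66 for SSEA1+ and -0.950 for SSEA1−. SSEA1+ and SSEA1−, all of type B, differed by -2.71 points (exact permutation p = 0.333, the smallest possible), by -1.53 over dense tiles only, and by -1.78 without SSEA1+ 2.

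**Figure D3:**
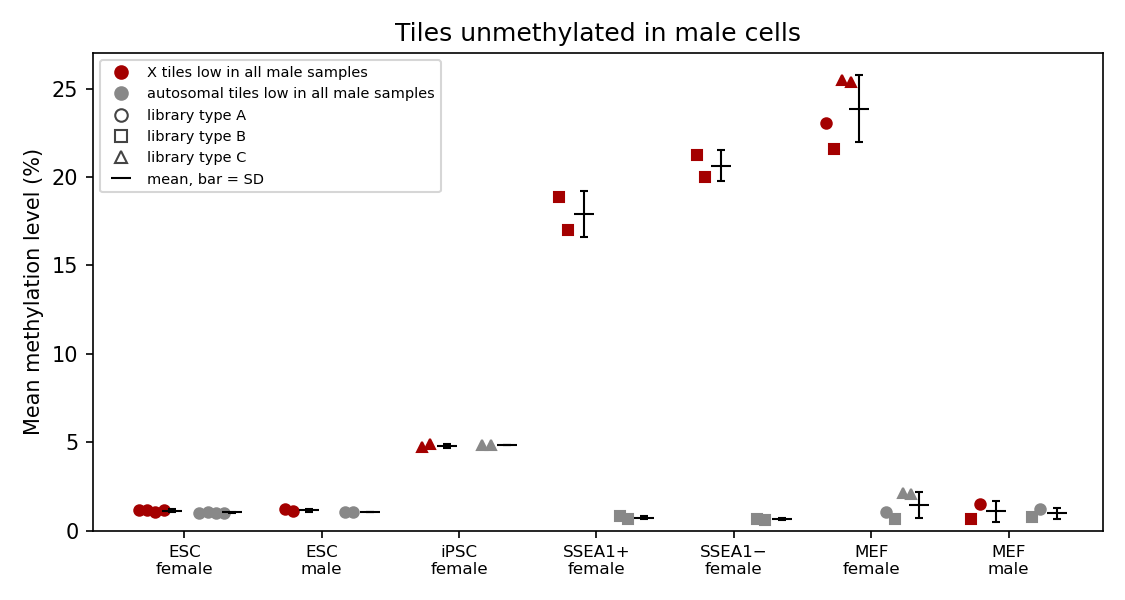
Mean methylation level (%, vertical axis) in each sample over the 254 X tiles (red) and 12520 autosomal tiles (grey) that were under 10% in all male samples; symbols give the library type and black marks the group mean with its SD. Female MEF, SSEA1− and SSEA1+ stood at 23.9%, 20.6% and 17.9% on the X, and iPSC at 4.80%, level with their autosomal background of 4.84%.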

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

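All tests of explanations in this part were chosen after the results were seen. Reads per chromosome, which no comparison of the report used, stood apart on chromosome 11 in both SSEA1+ libraries. Against female MEF of the same type, the median chromosome 11 tile had log2 reads higher by 0.19 in SSEA1+ 1 and 0.23 in SSEA1+ 2. The other libraries of that type lay at most 0.030 from 0, which argues against library type, and matching tiles on CpG number and methylation left 0.20 in both libraries, against at most 0.05 on the other autosomes. More copies of chromosome 11, or of a large part of it, in SSEA1+ cells may account for this. Of its 13 windows of 10 Mb, 12 lay above the 95th percentile of windows on other autosomes. However, the window from 10 to 20 Mb was at 0.01 and those from 50 Mb on at 0.20 to 0.27. The X of the male MEF library of the same type stood at only -0.26. The size of these log2 values therefore does not give the share of cells with more copies. In iPSC chromosome 11 was also the highest autosome, at 0.10 and 0.10 after matching, so a technical part stays open, and no karyotype was examined.

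Unmethylated tiles read higher in iPSC than in every other library. Over autosomal tiles low in male samples, the iPSC medians were 3.77% and 3.94%, and female MEF of the same type had at most 1.03%, which argues against library type alone. Gain of methylation at some of these tiles was tested by the share that were higher in iPSC than in those MEF. The share was 92.4%, too many for gain at a part of them alone. An error that reads a like share of unmethylated cytosines as methylated everywhere may account for the higher level. The 5th percentile over tiles was 1.57% in the lower iPSC library and 0 in every other library. Such an error would by itself raise most tiles, so the 92.4% cannot tell whether some tiles also gained methylation. Low iPSC values are therefore best read against their own background.

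Reads on the X were lower in iPSC than in female MEF of the same type, by log2 values of -0.29 and -0.27. Matching tiles on CpG number and methylation left -0.17 and -0.15, and the autosome farthest from 0 stood at 0.10. Male libraries stood between -0.36 and -0.21 after matching. In SSEA1+ 2 the X stood at -0.20 before matching and at -0.026 after it. For iPSC, a difference in covered tiles and a loss of an X in some cells cannot be told apart here, because the X lies outside the autosomal range by less than that range itself.

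The sex difference differed between ESC and MEF: by -14.7 points for the autosomal level, by -16.8 points for dense X tiles, and at 6041 tiles in the model. Among 12 groups and measures tested for a sample far from the others, 1 was found: an ESC sample at 1.03% over X tiles low in male samples, and chance gives about 1 in 20. For female ESC against female MEF, 1 of the 35 splits of those 8 samples, the real one, gave as many as 12897 tiles. The highest of the others gave 3289. A share of 1 in 35 is the smallest these splits can give, and the spread between samples may be technical. Chance is therefore not excluded by this test.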

How the results depend on the processing

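Tests chosen after seeing the data were those within library types (alone or with another measure), with library type as a term, over CpGs read in all samples, background corrected, without chromosome 11, and all on X tiles low in male samples. Of 261 alternatives other than leaving out 1 sample, 189 kept the direction and the side of the threshold, or the count within 1.5 times. The size of a difference could still move. For values with 1 number per sample, 2 samples against 2 or 4 cannot give an exact permutation p under 0.333 or 0.0667. Their side of the threshold of 0.05 was thus fixed by the sample numbers, and only the direction could change. Calls of named tiles were kept in 895 of 1013 tests, lost in 116 and turned in 2: chromosome 7 at 132635001 (SSEA1− against MEF) to -0.790 points over CpGs read in all samples, and X 99373001 to 0.213 with library type as a term. Named tiles absent under a setting were not counted. Of 87, 12 remained at a minimum of 10 reads (11 calls kept) and 38 over CpGs read in all samples (30 kept). All were chosen as the largest differences in these same libraries, so a kept call is partly given by the selection. The losses were uneven. Without SSEA1+ 1 and 2, 10 and 6 of 29 calls were lost, and without SSEA1− 1 and 2, 6 and 7 of 20. Without a female ESC library, 0 to 2 of 31 were lost. In what follows, tile counts are in the order female against male ESC, female against male MEF, ESC against MEF, iPSC against MEF, iPSC against ESC, SSEA1− against MEF, SSEA1+ against MEF, SSEA1+ against SSEA1−, iPSC against SSEA1+, and the difference of sex differences. A minimum of 10 reads left 12596 tiles, against 33545 in the main test, and gave 1455, 184, 2054, 1482, 770, 191, 224, 106, 1388 and 1030. Each count fell by a larger factor than the number of tiles, for example from 9004 to 1455 and from 12897 to 2054. Fewer tiles alone thus do not account for the lower counts. A minimum of 3 reads tested more tiles and gave 17345, 22561, 13934, 7096, 1135, 1573, 715, 12594 and 10939 for all but the sexes in MEF. Only CpGs read in all samples gave 4702, 185, 6891, 4776, 1788, 242, 384, 239, 4444 and 2667. In MEF the sexes split into 271 higher and 296 lower in the main test, 110 and 74 at 10 reads, and 208 and 43 with limma (251 in all); the cause was not tested. With limma, SSEA1− and SSEA1+ against MEF gave 248 and 573 and SSEA1+ against SSEA1− 287. Library type as a term gave 1129 for iPSC against ESC, 152 (59 higher, 93 lower) and 344 (118 higher, 226 lower) for SSEA1− and SSEA1+ against MEF, and 688 between them; the cause was not tested. Deviations of same-numbered samples had correlations of -0.270 to 0.0460 over 44 pairs. In groups of 2 the deviations mirror each other, so these pairs are not separate checks, and a pairing of samples is not excluded. A replicate block gave 323 tiles for the sexes in MEF (196 higher, 127 lower) and 153 and 333 for SSEA1− and SSEA1+ against MEF. It changed no other count of tiles by over 1.5 times. With a replicate block, female ESC against MEF kept differences of -19.2 points (autosomes), -32.1 (dense X tiles) and -22.7 (X tiles low in male samples), with 4 pairs too few for a p under 0.05; SSEA1− against MEF stood at -0.361 (autosomes) and -1.69 (X tiles low in male samples). Within library types the same 3 were -18.8, -31.6 and -21.9, female ESC and iPSC against male ESC -16.5, all female MEF and SSEA1 samples against male MEF 11.05 on dense X tiles, and SSEA1 samples against MEF -2.30 on X tiles low in male samples; none stayed under 0.05. The same held within types for ESC against MEF at 10 reads (-13.2 on autosomes, -22.9 on dense X tiles), over own CpGs (-18.1), read-weighted (-18.5) and over tiles of 20 CpGs (-35.2), for female ESC and iPSC against male ESC over own CpGs (-18.2) and read-weighted (-12.8), and for female MEF and SSEA1 samples against male MEF at 10 reads (16.2) and 20 CpGs (6.53). Too few relabellings remain within types for a p under 0.05 in any of these comparisons, so that loss was fixed by the sample numbers. The SSEA1 difference was also smaller within types, and the cause of this was not tested. On dense X tiles, female against male ESC moved from -3.51 to -1.44 points and SSEA1+ against SSEA1− from -1.79 to -0.804 at 10 reads, and SSEA1− against MEF from -3.52 to -2.06 within types. At 10 reads, SSEA1 samples against MEF differed by -4.51 points on X tiles low in male samples. Autosomal directions turned for the sexes in MEF (2.70 over each sample's own CpGs, 0.0800 read-weighted), SSEA1− against MEF (0.0550 within types, 0.331 there over own CpGs) and iPSC against SSEA1+ (6.83 over own CpGs, where the libraries cover different CpGs); iPSC minus ESC on X tiles low in male samples turned to -0.154 with the background subtracted. With samples exchanged, the position of SSEA1− moved to 3.11% (autosomes), 2.35% (X) and 5.92% (higher tiles), of SSEA1+ to 10.3%, 7.18% and 32.5%, and of iPSC to 69.1%, 82.5% and 139%. Leaving out 1 sample gave 337 to 918 tiles for the sexes in MEF, 378 to 1067 for SSEA1− and 343 to 1374 for SSEA1+ against MEF, 213 to 355 between them and 2873 to 6425 for the difference of sex differences. It gave -14.7 to -12.6 points for female ESC and iPSC against male ESC, 10.6 to 11.6 for all female MEF and SSEA1 samples against male MEF, and -5.36 to -3.83 for SSEA1 samples against MEF. For SSEA1+ against SSEA1− it gave -2.20 to -0.453 points on autosomes, -2.63 to -0.941 on dense X tiles and -3.64 to -1.78 on X tiles low in male samples. Between SSEA1+ and SSEA1−, leaving out 1 SSEA1+ sample turned the direction (188 higher, 167 lower), and leaving out the other left 37 higher and 176 lower. Promoter alternatives were not run, as no annotation on the build of the data was used here. Groups of 2 limit every exact test.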

Other observations

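Dense autosomal tiles of intermediate level in every MEF sample, chosen after seeing the data as those between 30 and 65%, numbered 15. Their mean level was 44.2% ± 2.84 in female MEF, 46.8% ± 0.299 in male MEF, 42.9% ± 1.30 in SSEA1− and 37.4% ± 3.40 in SSEA1+. It was 11.6% ± 1.84 in iPSC, 18.8% ± 2.39 in male ESC and 5.15% ± 0.613 in female ESC, where all 15 were under 20%. In male ESC, 3 of them stayed at 30% or more: chromosome 2 at 174125001 to 174126000 (54.2% ± 8.66), chromosome 10 at 12810001 to 12811000 (45.1% ± 6.47) and chromosome 11 at 11926001 to 11927000 (45.01% ± 19.9). Female ESC stood at 7.18%, 1.55% and 4.52% there, and iPSC at 24.7%, 15.3% and 12.9%. The tiles were selected on MEF, so a lower mean in other groups is partly given by the selection.

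Chromosome 11 was examined for methylation as well. The median difference of its tiles between SSEA1+ and MEF was -0.716 points, and that of the other autosomes -0.718 points. Of its 2482 tiles, 4.07% were called, against 2.66% elsewhere, and between SSEA1+ and SSEA1− 1.65% against 1.28%. The shares were not tested.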
